A study of Culter alburnus with 6 samples.

How the data were processed

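Total RNA was extracted with Trizol, messenger RNA was captured on poly-T beads, and cDNA primed with random hexamers was sequenced on an Illumina platform, per the labels' protocols. The authors deposited 1 table for the whole series, of raw read counts per gene locus in 6 libraries, with a locus identifier and a column for each sample per the file header. The aligner, the counting program, the genome build, the annotation version and the strand setting are not given in the sources used here. The values were whole numbers whose column totals differed between libraries, between 26611022 and 30795972 counts.

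Each column was matched to its sample by the sample title, and groups and replicate numbers were taken from those titles. The titles read wt or treat with a number, and wt was taken here as control and treat as cryopreserved. The identifiers are locus tags. All 28228 occur in the reference annotation of assembly ASM4018292v1, which has the same number of loci, but its symbol column repeats the locus tag for each of them. Before the data were examined, 35 gene lists were fixed for pathways, tissues and cell types of a fish embryo or larva. Of their 1740 symbols, 0 could be matched, so no list was tested and the planned set test (camera) was not run. The annotation was used for the order of loci and for their span, which includes introns and is not a transcript length. No coordinates are given, because the build behind the counts is not given in the sources used here.

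Even values were more frequent than odd ones among low counts. Of the counts from 1 to 20, 59.9% to 68.5% were even, depending on the library, against 49.9% to 50.6% of the counts from 101 to 1000. A deposited count therefore cannot be taken as one sequenced fragment, and limits that rest on counting error are too narrow to that extent.

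The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts as deposited, after edgeR's default expression filter by group, which left 21846 loci, and with TMM normalization. All 6 libraries entered a model with the group as the single term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and a second count added a change of at least 2-fold. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are scaled by the TMM factors, and so is the count expected for a locus in a library, which was taken from its mean CPM in the other 5. Log2 CPM, used for correlations and trends with span, had a prior count of 2. Intervals of fold changes came from limma-voom (limma 3.58.1). The rule for named genes, fixed before the data were examined, took the 8 largest increases and 8 largest decreases among named genes past the threshold with an average log2 CPM of at least 1 and no overlap between groups, further genes from the lists, and, without symbols, 2 identifiers in each direction under the same conditions. It named 0 loci.

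Alternatives fixed beforehand were DESeq2's size factors, upper-quartile factors, library size only, DESeq2 1.42.0 with its own filtering in place of edgeR's, limma-voom, no filter, a filter of at least 50 counts in at least 3 libraries, a threshold of 0.01, a block for the replicate number, and leaving out each library in turn. Alternatives added after seeing the data were leaving out control replicate 3 and cryopreserved replicate 1 together, DESeq2 on the loci kept by edgeR's filter, robust hyperparameters, library quality weights in limma-voom, 1 surrogate variable (sva 3.50.0), halved counts, and an offset for the trend with locus span. Every split of the 6 libraries into 3 and 3 was refitted in the same way, 10 splits in all with the real one, and once more with the offset for the trend with locus span. The fitting procedure was tested on simulated data, with counts drawn for the 21846 tested loci from their mean levels, dispersions and library sizes and with 200 loci changed by known folds. No pair of libraries agreed within sampling noise. The smallest chi-square per locus was 48.9, between control 2 and cryopreserved 3, where sampling noise gives about 1. The samples share replicate numbers across groups, but the labels state no pairing. For neighbouring positions, 10000 random sets were drawn within 5 classes of span for the loci at 0 in one library, and 1000 from all tested loci, without regard to span, for those at an unadjusted p under 0.05. Descriptive statistics and exact permutation tests used Python 3.11.15 with scipy 1.17.1.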

Results

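RNA sequencing was carried out on Culter alburnus (topmouth culter), a freshwater fish of the carp order, to ask how transcription in animals that were cryopreserved as embryos differs from that in controls. For cryopreservation, embryos were vitrified at the tail-bud stage, that is, cooled into a glass without ice crystals, and then rewarmed. The deposited table holds 28228 gene loci in 6 libraries, 3 from control animals and 3 from the cryopreserved group. The sample labels call the material embryos, whereas the study design speaks of larvae. The labels do not say whether the cryopreserved libraries come from water-bath or from laser warming with gold nanorods. Nothing in the labels says that the 3 libraries of a group come from separate batches of animals, so p-values measure the spread between these libraries, which may be technical.

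Library totals were 27598664, 26611022 and 29951314 counts in control replicates 1, 2 and 3, and 30795972, 28928972 and 29641070 counts in cryopreserved replicates 1, 2 and 3. Between 20639 and 21985 loci had at least 10 counts in a library, and 2609 loci were at 0 in all 6. The 10 most abundant loci of each library took 11% ± 4.02 of the counts in the controls and 12.6% ± 3.70 in the cryopreserved group (SD, n = 3 each). Across 6 such library measures, which were these totals, shares, numbers of detected and of undetected loci, and the trend with locus span described further on, the exact two-sided permutation p lay between 0.3 and 0.9, and every Benjamini-Hochberg adjusted value was 0.9. An exact test of 3 libraries against 3 cannot give a p below 0.1.

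No locus was called different between the cryopreserved and the control libraries by edgeR, and 3 or 5 were called by DESeq2, depending on the filter. Of 21846 loci tested, 0 passed an adjusted p of 0.05 with edgeR's quasi-likelihood test, and so 0 passed it with a change of at least 2-fold. At an unadjusted p under 0.05 there were 127 loci, of which 84 were higher and 43 lower in the cryopreserved group. Uniform p-values would give 1092, and the other splits of the 6 libraries into 3 and 3 gave between 186 and 3505. As this number varies so widely between splits, its low value does not show that the groups are more alike than chance would make them. The balance of higher and lower loci turned when 1 library was left out. It was 63 higher and 67 lower without cryopreserved replicate 1, and 133 and 149 without cryopreserved replicate 3. It leaned further to higher loci without cryopreserved replicate 2, with 358 and 81, and without control replicate 2, with 212 and 51, and was 182 and 97 without control replicate 3 and 77 and 45 without control replicate 1. With 1 surrogate variable, an alternative added after seeing the data, it was 55 and 64. With limma-voom 0 loci passed, and 100 were at an unadjusted p under 0.05. DESeq2, run without edgeR's filter on 25538 loci, called 5, each with a higher fitted level in the cryopreserved group, and had 364 at an unadjusted p under 0.05. On the loci kept by that filter, an alternative added after seeing the data, DESeq2 called 3 of these 5 and no others, and had 255 at an unadjusted p under 0.05. The median fitted log2 fold change over all tested loci was 0.02.

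The loci carry locus tags only, and neither the count table nor the reference annotation pairs these tags with gene names. The loci described here were therefore not assigned a function. No locus met the rule for naming fixed before the data were examined, which required an adjusted p under 0.05. The 4 loci below were chosen after their values were seen, as the pair in each direction with the smallest unadjusted p among loci with an average of at least 1 log2 CPM and no overlap between the groups.

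ABG768_010759 had the smallest p of all tested loci. Its level was 6.35 ± 1.51 CPM in the controls and 45.8 ± 16.2 CPM in the cryopreserved libraries (SD, n = 3 each), a ratio of 7.22. The fitted log2 fold change was 2.85 with a standard error of 0.39, and the adjusted p was 0.999955 with edgeR and 2.07e-06 with DESeq2. ABG768_021918 stood at 0.487 ± 0.353 CPM in the controls and at 12.2 ± 7.87 CPM in the cryopreserved libraries (SD, n = 3 each), a log2 fold change of 4.65 ± 0.80 (SE). Its adjusted p was likewise 0.999955 with edgeR and 2.07e-06 with DESeq2. Over the 22 alternative settings the adjusted p ranged from 1.24e-06 to 1 for the former and from 2.07e-06 to 1 for the latter, with the lowest values from DESeq2. By the way they were chosen, both loci had higher CPM in 3 of 3 cryopreserved libraries than in any control. The locus that follows ABG768_010759 in the annotation was also higher in each cryopreserved library, at 12.1 to 17.8 CPM against 4.25 to 10 CPM, with a log2 fold change of 1.32 and an edgeR adjusted p of 0.999955. The preceding one had a log2 fold change of -0.25. The locus that follows ABG768_021918 had one of 1.17 with overlapping groups, and the preceding one had too few counts to be tested.

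In the other direction, ABG768_009055 had 57.3 ± 15.7 CPM in the controls and 20.5 ± 4.8 CPM in the cryopreserved libraries (SD, n = 3 each), a log2 fold change of -1.48 ± 0.34 (SE). ABG768_011782 had 6.82 ± 0.908 CPM and 1.19 ± 0.807 CPM (SD, n = 3 each), a log2 fold change of -2.50 ± 0.66 (SE). Neither passed with edgeR, where both adjusted p-values were 0.999955, or with DESeq2, where they were 0.446 and 0.247, or 0.418 and 0.324 on the loci kept by edgeR's filter. By the same choice, each was lower in 3 of 3 cryopreserved libraries than in any control. The loci on both sides of ABG768_009055 and of ABG768_011782 had log2 fold changes between -0.17 and 0.18. Whether any of these loci shares reads with a near-identical copy was not checked, since no genome sequence was used here.

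**Figure D1:**
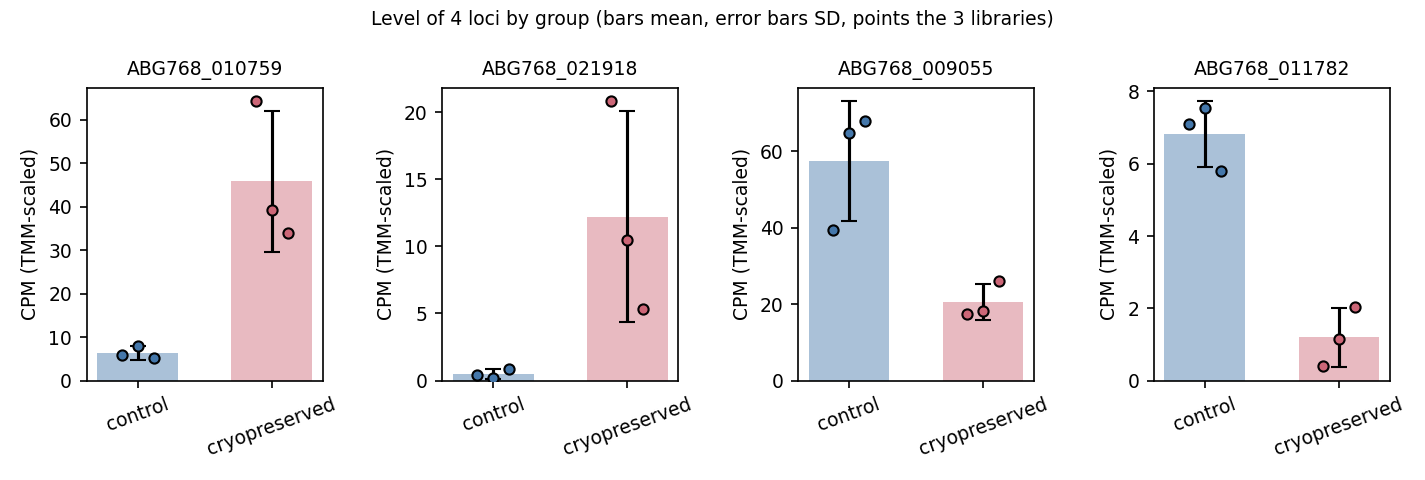
CPM (counts scaled to library size with TMM factors, linear axis from 0) of 4 loci in the control and cryopreserved libraries; bars are means, error bars SD and points the 3 libraries of each group. The 4 loci were chosen among those where the groups do not overlap, and none passes an adjusted p of 0.05 with edgeR.

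The remaining 3 of the 5 loci called by DESeq2 without edgeR's filter had few or no control counts, and 1 of them was also called with the filter. Their control libraries held between 0 and 12 counts, and their cryopreserved libraries between 2 and 341. DESeq2's adjusted p was 0.00536 for one and 0.0297 for the other pair. For all 5 called loci, every cryopreserved library lay above every control, although 1 of them had 2 counts in cryopreserved replicate 1, below the limit of 3 that a count of 0 allows. Loci with no count in any control and at least 10 in each cryopreserved library numbered 5, and there were 0 of the converse kind. The other 9 ways of parting the 6 libraries into 3 and 3 gave between 0 and 6 of the one kind and between 0 and 3 of the other.

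Abundant loci varied less than scarce ones. The tested loci were parted into 5 classes of equal size by abundance. In the most abundant class, 1.72% had a fitted change above 2-fold in either direction, with a median standard error of 0.35 log2 units. In the least abundant class these values were 21.8% and 0.94. Over all tested loci, 1418 had a fitted change above 2-fold, 799 higher and 619 lower, without passing the test. The direction of this balance turned without any 1 of the cryopreserved libraries, to 601 higher and 707 lower without replicate 1, 1593 and 1702 without replicate 2, and 1153 and 1439 without replicate 3. Without control replicate 2 it was 2185 higher and 952 lower. Among the 100 most abundant loci, 6 had a fitted level more than 2-fold higher in the cryopreserved group and 0 more than 2-fold lower. None of these 100 loci had an unadjusted p under 0.05, and without cryopreserved replicate 1 the number above 2-fold was 0. It was 17 without control replicate 3 and 13 without cryopreserved replicate 2.

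The common biological coefficient of variation was 0.553. With limma-voom, the median half-width of the 95% interval of a log2 fold change was 1.16, and 21.1% of tested loci had an interval that lay wholly within a 2-fold change in either direction. In counts simulated for this comparison over 21846 loci with the spread measured here, the test recovered 0% of 50 loci changed by 2-fold, 10% of those changed by 4-fold, 64% at 8-fold and 88% at 16-fold, with 4 calls among unchanged loci. Changes of 4-fold or less in single loci were thus mostly not recovered in simulated counts. These counts were drawn independently for each locus, without differences between libraries that many loci share. In the real fit 127 loci had an unadjusted p under 0.05, where uniform p-values would give 1092. The recovered shares may therefore not hold for the real libraries.

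The groups did not separate in overall expression either. Spearman's rho of log2 CPM had a median of 0.897 over the 6 pairs of libraries within a group and 0.910 over the 9 pairs between groups. The pair with the highest value was control 2 and cryopreserved 3, at 0.974, followed by control 1 and cryopreserved 2, at 0.965. Control 3 and cryopreserved 1 stood apart from the rest. They had the lowest rho of all pairs with each other, 0.811, and the highest rho of either with any other library was 0.910 and 0.905. Their 100 most abundant loci took 35.3% and 34.9% of the counts, against 21.5% to 25.2% in the other 4 libraries. Without both of them edgeR called 0 loci, with 456 at an unadjusted p under 0.05. In simulated counts of 2 against 2 libraries over 21846 loci, the test recovered 0% of 4-fold, 4% of 8-fold and 34% of 16-fold changes. That simulation took its spread from all 6 libraries, control 3 and cryopreserved 1 included. It had the library sizes of control 1, control 2, cryopreserved 1 and cryopreserved 2. It therefore does not give the recovery of the fit without control 3 and cryopreserved 1, and which changes that fit could miss was not measured.

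**Figure D2:**
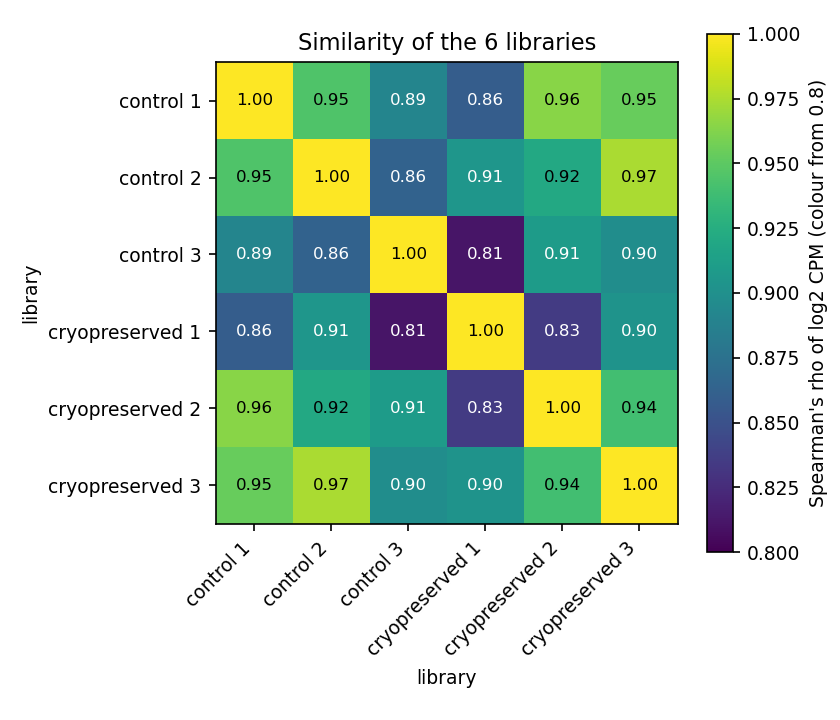
Spearman's rho of log2 CPM between each pair of the 6 libraries, as colour (scale from 0.8 to 1) and number. The 2 highest values between different libraries, 0.974 and 0.965, join a control with a cryopreserved library.

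Fewer loci separated the groups than separated any other split of the same libraries. For 801 of the 21846 tested loci, or 3.67%, the CPM values of the groups did not overlap, with 403 loci higher and 398 lower in the cryopreserved group. A split of 6 values into 3 and 3 gives 10% by chance. A locus without tied values separates exactly 1 of the 10 splits, so a high share in 1 split lowers the others. The low share for the groups therefore does not show that they are more alike than chance would make them. The other 9 splits gave 4.60% to 28.5%, and the highest was control 1, control 3 and cryopreserved 2 against the rest.

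**Figure D3:**
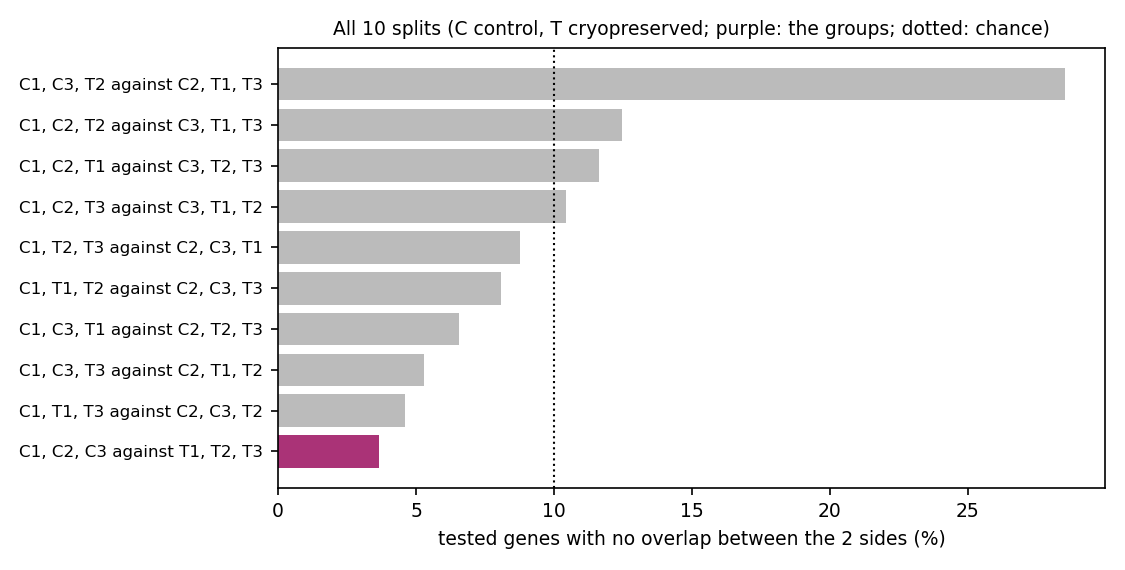
Share of the 21846 tested loci whose CPM values do not overlap between the sides, for each of the 10 splits of the 6 libraries into 3 and 3 (C control, T cryopreserved, with replicate numbers; dotted line, 10% expected by chance). The split by group has 3.67%, the lowest, and the highest split has 28.5%.

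A set of loci was missing from cryopreserved replicate 1. In that library 165 loci were at 0 counts that had at least 50 counts in each of the other 5 libraries. The corresponding number was 28 for control replicate 3, 3 for control replicate 1 and 0 for the remaining 3 libraries. Counted instead as loci below an eighth of their mean CPM in the other 5 libraries, zeros included, there were 532 in cryopreserved replicate 1 and 483 in control replicate 3, against 3 to 62 in the other 4 libraries. In the other direction, 26 loci of cryopreserved replicate 1 lay above 8-fold that mean, against 0 to 2 in each other library. These too had at least 50 counts in each of the other 5 libraries. Of the 165 loci, 24 had at least 1000 counts in every other library. The limit that a count of 0 allows, 3 counts of the total, is 0.123 CPM in this library, on the TMM-scaled CPM used throughout, and covers counting error only. Against that limit, the 165 loci were a median of at least 64.0-fold lower than their mean over the other 5 libraries. Chosen without regard to the other 2 cryopreserved libraries, 179 loci were at 0 in cryopreserved replicate 1 and had at least 50 counts in each control. Of these, 0 were at 0 in either of the other 2 cryopreserved libraries, whose mean had a median log2 ratio to the control mean of -0.07 (interquartile range -0.39 to 0.16), and 13 had a ratio below -1.

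Levels also followed the span of the locus in several libraries, in both directions. Loci were parted into 5 classes of equal size by span, introns included, and each library's deviation from the locus median over the 6 libraries was taken. In control replicate 3 the longest class differed from the shortest by -0.74 log2 units, whereas in cryopreserved replicate 1 it differed by 0.41 and in control replicate 2 by 0.24. It differed by -0.16 in cryopreserved replicate 2, and by -0.04 and 0.02 in control replicate 1 and cryopreserved replicate 3. Across loci, which are not independent replicates, Spearman's rho of the deviation with span was -0.339 in control 3, 0.258 in control 2, 0.198 in cryopreserved 1 and -0.127 in cryopreserved 2. The difference averaged -0.18 ± 0.50 in the controls and 0.09 ± 0.29 in the cryopreserved group (SD, n = 3 each; exact two-sided permutation p = 0.5, adjusted 0.9).

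**Figure D4:**
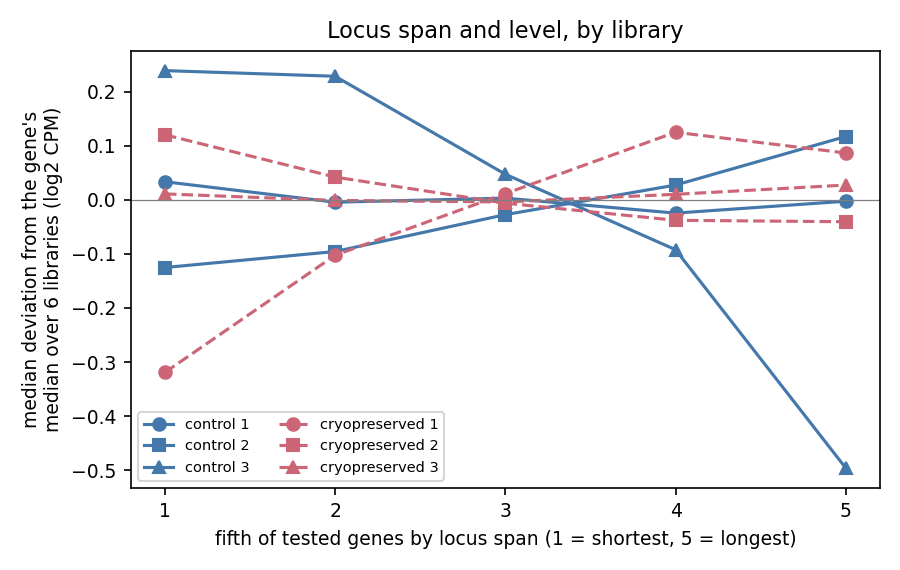
Median deviation of log2 CPM from each locus's median over the 6 libraries, by class of the tested loci from the shortest (1) to the longest span (5); lines are libraries, solid for control and dashed for cryopreserved. Control 3 falls from 0.24 to -0.50, cryopreserved 1 goes from -0.32 to 0.09 and control 2 from -0.13 to 0.12.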

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

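The count of loci past the threshold was 0 under every alternative with edgeR or limma-voom, planned or added, and so was the count with at least 2-fold change. DESeq2 gave 5 for both counts over 25538 loci, and 3 on the loci kept by edgeR's filter, an alternative added after seeing the data. The number at an unadjusted p under 0.05, 127 as reported, was 364 with DESeq2 without the filter, 255 with DESeq2 on the loci kept by it, 253 with edgeR without a low-count filter and 80 with the stricter filter. Leaving out 1 library at a time gave 122 to 439, with the highest value without cryopreserved replicate 2; it was 282 without cryopreserved replicate 3, 279 without control replicate 3 and 263 without control replicate 2, with 0 calls in each case. Of the alternatives added after seeing the data, leaving out control replicate 3 and cryopreserved replicate 1 together gave 456 and library quality weights in limma-voom gave 660. The cause of these shifts was not tested, except that the filters change the number of loci tested, to 25619 without one and 19079 with the stricter one. With the replicate number as a block the calls were again 0 and the number at an unadjusted p under 0.05 was 75, of which 39 were higher and 36 lower. Same-numbered libraries did not deviate together (correlations of -0.14, -0.38 and -0.05 for numbers 1, 2 and 3). These values show no pairing by number, but 3 of them are too few to exclude one. The log2 fold change ranged over 22 alternatives from 2.39 to 3.06 for ABG768_010759, 4.02 to 5.37 for ABG768_021918, -1.71 to -1.03 for ABG768_009055 and -3.13 to -2.09 for ABG768_011782. Their sign is no test, since loci without overlap between groups were chosen. The first pair passed the threshold with DESeq2, with and without the filter. The difference between the median rho within and between groups, -0.01 as reported, moved by less than the spread between pairs with Pearson's r or a stricter filter, and another prior count leaves the ranks behind rho as they are. The gene lists gave no value under any setting because no symbol could be matched.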

Other observations

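The tests in this part were chosen after the results were seen. Only for the refit of the leading split with the trend with locus span removed was the prediction written before that refit. The loci missing from cryopreserved replicate 1 held more neighbouring pairs than random sets did, and tended to be short. Most of them had no neighbour in the set. Random sets take no account of neighbouring loci whose levels vary together. Among the 165 there were 13 pairs of neighbouring loci, against a mean of 1.36 and a maximum of 7 in 10000 random sets of the same size and the same number per span class (permutation p = 0.0001, the smallest these sets can give). Their median span was 3450 bases, against 11010 for the other loci with at least 50 counts in each of the other 5 libraries. The 28 loci missing from control replicate 3 alone held 0 neighbouring pairs and were long, with a median span of 42149 bases.

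A loss shared by the cryopreserved group is argued against by the 179 loci at 0 in cryopreserved replicate 1 and at 50 or more counts in each control, a set that leaves the other 2 cryopreserved libraries free. Their median log2 ratio to the controls over it was -0.0664, with 0 loci at 0 in either. Too few distinct molecules in the library would remove scarce loci before abundant ones, yet 97.3% of loci with an expected count over 50 to 200 were detected while 35 loci expected above 640 counts were not. A lower yield of short loci stays open. Of the 165 loci, 61.8% lie in the shortest of 5 span classes of the loci with at least 50 counts in each of the other 5 libraries. The share at 0 goes from 3.11% in that class to 0.183% in the longest. When all tested loci are parted by span, the shortest class stands at -0.32 log2 units in this library. However, 96.9% of the former class were detected, whereas the 165 loci were a median of at least 64.0-fold lower than their mean over the other 5 libraries. A small loss over the whole class does not by itself account for them. A transcript class, tissue or stage absent from the animals of this library, or a difference in how its reads were counted, remain possible and were not tested, since the loci have no names, and too few molecules stays open for the loci expected at 640 counts or fewer.

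The lower level of long loci in control replicate 3 was present in each of 5 abundance classes, where the longest loci differed from the shortest by -0.75 to -1.17 log2 units. With the trend with span removed by an offset, edgeR still called 0 loci between the groups, with 143 at an unadjusted p under 0.05. Partly fragmented RNA or another mixture of cell types may lie behind the trend. Neither was tested, because the span includes introns and no read coverage was used, and no biological explanation was tested.

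The split by group gave the fewest loci of any of the 10 splits, both at an unadjusted p under 0.05 (127, highest other 3505, as many in 10 of 10 splits) and without overlap (801, highest other 6233, as many in 10 of 10), and DESeq2's 5 calls without the filter were matched in 9 of 10, too few splits for a share under 0.05. EdgeR called 0 loci in every split, with or without a 2-fold change (highest other 0), so the count of splits with as many says nothing there. Control 1, control 3 and cryopreserved 2 against the rest gave 1025 DESeq2 calls, the most of the 10 splits. This split was singled out as the highest of the 10 by the same values, and some split must lead. Its calls therefore do not test whether a structure of the samples crosses the groups. Control 3 and cryopreserved 1, which stand apart, lie on opposite sides of this split, and how far they alone set it was not tested. The same split parts the libraries by the sign of their trend with locus span, although control 1 and cryopreserved 3 lie near 0 at -0.04 and 0.02. That trend as the whole source of the split is argued against by a refit with an offset, which brought the difference between the longest and shortest class to between -0.05 and 0.05 in each library and left the split with 3314 loci at an unadjusted p under 0.05 and 0 called. RNA quality beyond this trend, exchanged labels of control 2 and cryopreserved 2 (3505 loci at an unadjusted p under 0.05) and a group difference hidden by control 3 and cryopreserved 1 (456 without both, 0 called by edgeR) stay open, as no value here decides between them.

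The 127 loci at an unadjusted p under 0.05 held 4 pairs of neighbours with a fold change of the same sign, against a mean of 0.337 in 1000 random sets (permutation p = 0.001, the smallest these sets can give). The 127 loci of smallest p in each of the other 9 splits held between 0 and 7 such pairs, so neighbouring pairs are not peculiar to the split by group.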
